A study of Homo sapiens with 3 samples.

How the data were processed

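RNA from 3 stable LoVo lines (pLKO.1 control, sh1 and sh2 against TEAD4) was labelled with Cy3 and hybridised to 1 single-colour Agilent array per line, per the labels. Groups were taken from sample titles. Nothing stated that any sample was replicated, so differences are given by size. A limma fit that takes the hairpins as replicates is given as an alternative. With 1 array per line, the precision of the differences beyond the scanner's error cannot be measured here.

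The deposited scanner files hold spot intensity on a linear scale, made by the authors with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. Per the file headers, the processed intensity had a spatially detrended background subtracted, was detrended multiplicatively, and took surrogate values for spots at background, with no normalization between arrays. Surrogates give dim spots a floor, so differences of dim genes are set partly by it. The deposited files also hold other columns, namely quality flags of 0 or 1 per spot (well above background, outlier, saturated), per the file headers. The deposited series table holds log2 values by the authors, whose columns share a median of 5.14 and correlate at 0.9997, 0.9999 and 0.9998 with the scanner values of the same arrays. Its equal distributions show quantile normalization without centring per probe, while the steps after extraction were not given in the sources used here, and direction does not apply to single-colour values.

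From the scanner files, log2 of the processed signal minus each array's 75th percentile was used. Control spots and outlier spots (427, 496 and 389 on the control, sh1 and sh2 arrays) were left out, no spot was saturated, and repeated spots of a probe were averaged. The 75th percentile signals were 495, 537 and 461. Among probes with 10 spots, the median SD of log2 signal between spots was 0.04, 0.04 and 0.05. The scanner's error model, with its multiplicative part set at 10% per the file headers, gave the ± values, which leave out differences between cultures. The array build was not given in the sources used here. Probe accessions were named through a RefSeq gene table for assembly GRCh38.p14, used for names and not for positions. Of 50599 probes, 28174 matched 1 gene each (20503 genes) and 22425 had no name there; of 25219 probes with a coding RefSeq accession, 24546 matched. A gene was represented by its probe with the highest mean signal and counted as measured when that probe was well above background on at least 1 array, which left 16331 genes.

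A gene not well above background in a group has only a bound there. The bound is the brighter group's value over the dim array's lowest signal among probes well above background, or the probe's own signal if higher, and is written as at least N-fold. Genes at least 2-fold different were counted per hairpin, in both hairpins and between hairpins. Another measured probe existed for 24 of the genes at least 2-fold different the same way in both, and of these 28 probes 21 had the same sign in both and 16 passed 2-fold the same way. Overlap was set beside 1000 simulated sets and beside independent lists. The 19 gene lists were described by the percentile of their median among 10000 random lists of the same size matched on mean signal. They cover the TEAD family, YAP/TEAD targets, Hippo components, epithelial and mesenchymal genes, TGF-beta, Wnt and stem cell, intestinal differentiation, cell cycle, p53, interferon, stress, hypoxia, cholesterol, NF-kB, AP-1, integrins and matrix, non-epithelial and housekeeping genes.

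The groups, measures, lists, alternative settings and rule for named genes were set before the data were examined. The rule took the TEAD genes, the 15 highest and 15 lowest genes by the smaller of the hairpins' differences among those past 2-fold in both and well above background on all 3 arrays, and up to 5 genes each way given as bounds. It also took the 5 highest and 5 lowest between hairpins, up to 4 members per list with the largest mean difference, and VIM, CDH1, CCN1, CCN2, ANKRD1, AXL, AMOTL2, LATS2, YAP1 and WWTR1. Some genes this rule takes are not reported here. Genes named in the closing section outside this rule were chosen after their values were seen.

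The alternatives were normexp background correction with offset 50, quantile normalization, median centring and the authors' deposited log2 table. Others were no filter or a stricter filter on dim probes, the mean over a gene's probes, and outlier spots kept. The last were a 1.5-fold threshold, a 2-fold difference that also lay beyond 1.96 scanner errors, and limma with the hairpins as 2 replicates. A floor on dim values, and counts with dim genes at their bounds, were added after the data were seen. The counting of genes past 2-fold in both was tested on simulated data over 16331 genes with 200 planted changes: it recovered 28% at 2-fold, 88% at 3-fold, 96% at 4-fold and 100% at 8-fold, and called 2.63% of unchanged genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.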

Results

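Gene expression was measured in LoVo cells, an established human colorectal cancer line, that stably carried the pLKO.1 control or 1 of 2 short hairpin RNAs against TEAD4, named sh1 and sh2. TEAD4 is a TEA-domain transcription factor that works with the coactivators YAP and TAZ at the end of the Hippo pathway. Each of the 3 groups had 1 single-colour Agilent array, so differences have no replicate check and are given by their size. One label of the sh2 sample names sh1, while its title, source and description name sh2, and it is treated as sh2. On the control, sh1 and sh2 arrays, 31168, 29840 and 28497 of 50599 probes were well above background, and the median probe signals were 50.3, 53.4 and 41.7. All arrays lay on 1 slide, with the control and sh1 in the same scan and sh2 in another scan. Sh2 and its scan therefore cannot be told apart, whereas sh1 and the control were compared within a scan. Differences are log2 values of a hairpin array minus the control array, and each ± is the scanner's error for that difference.

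TEAD4 transcript was lower in both hairpin lines, which was the first question the design posed. It was 2.45-fold lower in sh1, a difference of -1.29 ± 0.20, and 2.62-fold lower in sh2, a difference of -1.39 ± 0.20. The hairpins differed from each other by 0.09 ± 0.20 for this gene, less than the error. The paralogs did not follow: TEAD1 stood at -0.02 and -0.22, TEAD2 at 0.47 and 0.21, and TEAD3 at 0.27 and 0.26 in sh1 and sh2. Over the 4 family members the median difference was 0.12 in sh1 and -0.01 in sh2. A single probe, read from transcript NM_003213, reported TEAD4, and its place relative to the hairpin targets was not known.

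**Figure D1:**
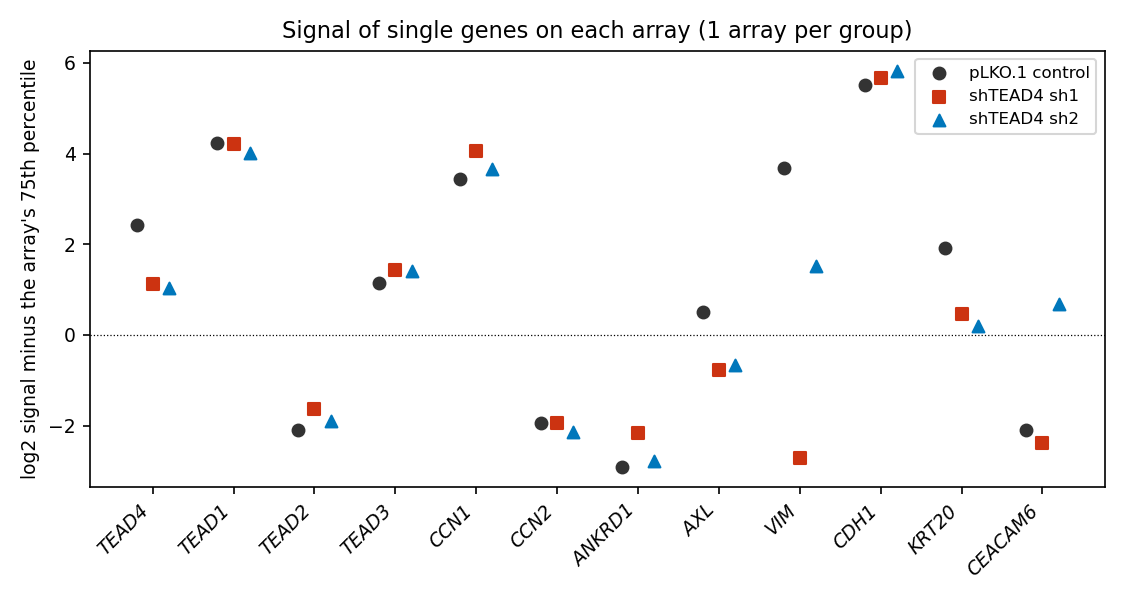
Normalized log2 signal (y axis, log2 signal minus the array's 75th percentile) of 12 genes (x axis) on the control (circles), sh1 (squares) and sh2 (triangles) arrays, with 1 point per array and no error bars. TEAD4 lies lower in sh1 by -1.29 and in sh2 by -1.39, and VIM by -6.38 and -2.15.

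VIM, MSN, PXDN and ITGA4 were among the genes lowest with both hairpins. VIM, the intermediate filament vimentin, was 83.2-fold lower in sh1 (-6.38 ± 0.21) and 4.43-fold lower in sh2 (-2.15 ± 0.20). MSN, encoding the membrane-cytoskeleton linker moesin, differed by -4.99 ± 0.30 and -1.74 ± 0.21. VIM and MSN were each read by 1 probe with 1 spot, so artifacts of single spots stay open for them. PXDN, a peroxidase that crosslinks collagen IV, differed by -2.36 ± 0.24 and -3.02 ± 0.29, and its other probe by -4.63 and -3.27. ITGA4, the integrin alpha 4 subunit, was not well above background with either hairpin, and was at least 29.5-fold lower in sh1 and at least 22.3-fold lower in sh2. In all, 229 of 16331 measured genes were at least 2-fold lower with both hairpins by measured values, and 49 of these were well above background on all 3 arrays. With dim genes taken at their bounds the number was 117.

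The growth factor PGF differed by -2.85 and -2.0, the secreted glycoprotein FSTL1 by -2.66 and -1.96, and the chloride channel CFTR by -2.74 and -1.81. CAVIN3, a caveolar coat protein, differed by -4.06 and -1.73, the lysosomal protease CTSZ by -2.09 and -1.71, and the membrane-associated protein BASP1 by -3.17 and -2.06. The homeobox gene HOXB8 differed by -2.37 and -2.07, and the ubiquitin-conjugating enzyme UBE2E1 by -2.15 and -2.02. The cancer-testis antigen MAGEA2B differed by -4.88 and -2.12, and its other probe by -3.38 and -1.36. SLC17A9 (-2.33 and -1.73) and the antisense RNA GHRLOS (-1.69 and -1.75) completed the set with TAF5L, whose probes did not concur, at -1.88 and -1.82 by one and -0.07 and -0.12 by the other. Other genes that were dim on at least 1 hairpin array had large bounds: HTR3D was at least 12.4-fold lower in sh1 (its other probe at -2.69 and -3.10 by measured values), LY6K at least 18.3-fold lower in sh1, CTSG at least 9.48-fold lower in sh2 and KIR3DL3 at least 8.56-fold lower in sh2.

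Fewer genes, 77, were at least 2-fold higher with both hairpins by measured values, 26 of them well above background on all 3 arrays, and 32 were with dim genes at their bounds. The long noncoding RNA LETR1 was 76.2-fold higher in sh1 (6.25 ± 0.31) and 40.9-fold higher in sh2 (5.35 ± 0.31). Its control signal, from 1 spot, was 20.2, near the lowest signal well above background on that array, 15.1. So were those of LGI4 (23.8), ATP8A2 (17.2) and NHEG1 (16.9), also from 1 spot each, so these folds rest on control values near the floor. JAKMIP3 stood at 4.75 and 3.36, LGI4 at 3.91 and 2.33, and ATP8A2, a phospholipid flippase, at 2.32 and 2.39, with its other probe at 1.0 and 0.87. ITGA1, the collagen-binding integrin alpha 1 subunit, stood at 1.68 and 1.22, and the complement component C3 at 1.21 and 2.07, with its other probe at 1.09 and 2.17. HAUS3 (1.73 and 1.73), KCNJ18 (1.54 and 1.54), GPR20 (1.40 and 1.59), CYP4F30P (1.97 and 1.38), NHEG1 (1.51 and 1.26), TRIM29 (1.29 and 1.40) and COQ8B (1.20 and 1.5) were higher as well. APOL6 stood at 2.57 and 2.90 by one probe, but at -0.36 and 0.05, and -1.17 and -0.25, by its others. TRMT2B stood at 1.74 and 1.46 by one probe and at -0.91 and -0.59 by another. Among genes not well above background in the control, SULT6B1 was at least 18.7-fold higher in sh1 and at least 6.98-fold in sh2, and the transcription factor RUNX3 at least 3.04-fold and at least 2.89-fold. The bounds for PCDH11X were at least 3.59-fold and 2.02-fold, for CIMIP2B at least 2.52-fold and 2.02-fold, and for RDM1P5 at least 2.01-fold and 1.95-fold.

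Against the control, 231 genes were at least 2-fold higher and 443 lower in sh1, and 359 higher and 679 lower in sh2, by measured values. With dim genes at their bounds these were 151, 238, 262 and 304. With each array centred on its median in place of its 75th percentile, sh2 had 522 higher and 519 lower genes, and the median of all genes moved to 0.06 in sh1 and 0.22 in sh2. Both hairpins shared the control array, so their overlap was set beside 1000 simulated sets of unchanged arrays whose noise came from the sh1 minus sh2 difference. The 229 genes lower with both lay inside the simulated range of 191 to 244 (mean 215), and the 77 higher with both lay below its range of 187 to 243 (mean 215). Independent lists of these sizes would share 18.4 lower and 5.08 higher genes, a figure that leaves out the shared control. The differences of the hairpins correlated across genes at r = 0.46 (simulated 0.50), with Spearman's rho 0.38, a covariance of 0.14 (simulated 0.17) and the same sign in 63.8% of genes (simulated 66.6%). Genes are not independent replicates. The overlap was no larger than the simulated ranges of unchanged arrays, so its size does not show a response common to the hairpins. How much of the overlap came from the shared control cannot be told, since the control could not be split. The simulated noise also holds any real difference between the hairpins and between their scans. It was given to the control too, although the control and sh1 shared a scan. A common response is therefore not excluded either. Among genes well above background on all 3 arrays, 26 were higher and 49 lower with both, against simulated means of 58.4 and 58.5.

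**Figure D2:**
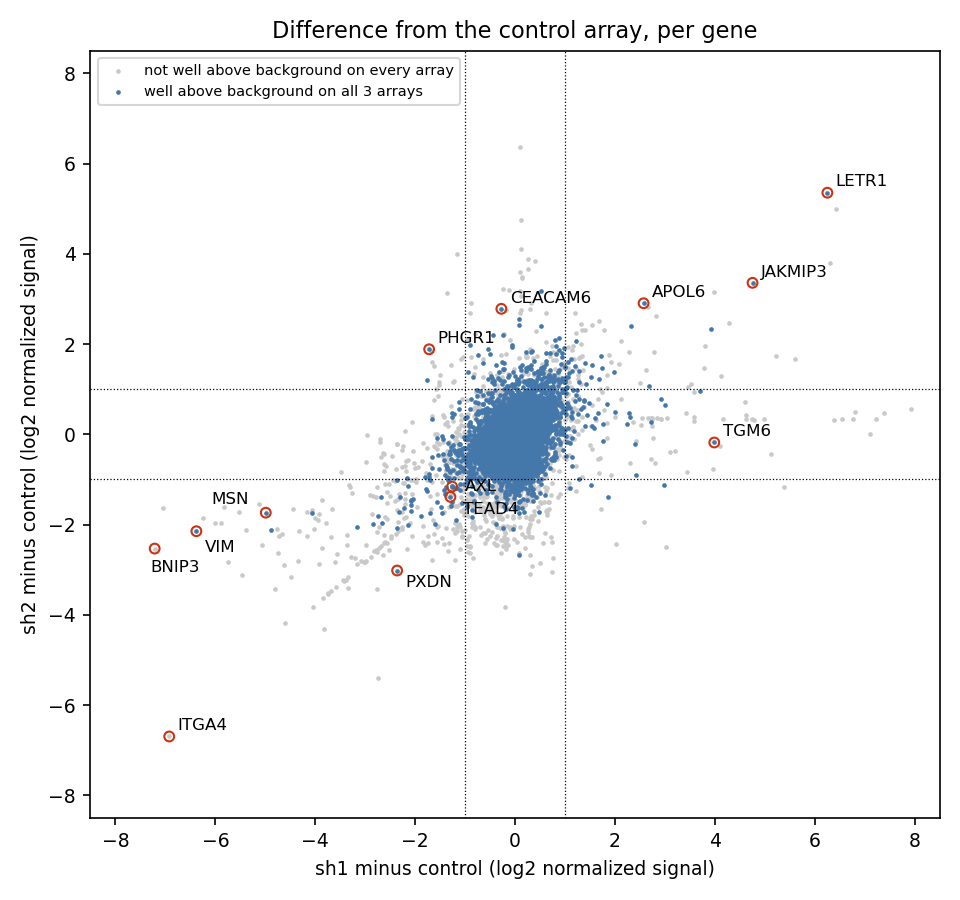
Log2 difference from the control array in sh1 (x axis) and sh2 (y axis), with 1 point per measured gene (16331), blue where well above background on all 3 arrays and grey otherwise, and dotted lines at the 2-fold threshold. VIM, MSN and BNIP3 lie farther from the control in sh1 than in sh2, while CEACAM6 lies at -0.27 in sh1 and 2.78 in sh2; grey points are measured values and can exceed the bounds in the text.

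Widely used readouts of YAP and TEAD mostly stayed within 2-fold of the control. Of 26 measured list members, 2 were at least 2-fold lower with both hairpins and none higher. These were AXL, a receptor tyrosine kinase, at -1.26 ± 0.20 and -1.16 ± 0.21, and CCDC80, at -1.69 in sh1 and at least 3.06-fold lower in sh2. The canonical targets CCN2 (0.00 and -0.20), CCN1 (0.63 and 0.23), ANKRD1 (0.75 and 0.12), AMOTL2 (0.41 and 0.22) and LATS2 (0.51 and 0.18) were not lower by that size, and FJX1 stood at 0.74 and 0.59. AMOTL1 was lower by 2-fold in sh2 alone, at -0.13 and -1.32. The list's median was 0.05 in sh1, percentile 60.8 among 10000 random lists matched on signal, and 0.14 in sh2, percentile 96.9. Percentiles of this kind describe these arrays and are not tests.

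Upstream Hippo pathway components had medians of 0.13 in sh1 and 0.16 in sh2, at percentiles 96.6 and 98.9. YAP1 stood at 0.02 and 0.34, WWTR1, which encodes TAZ, at 0.16 and 0.27, SAV1 at 0.37 and 0.63, WWC2 at 0.42 and 0.55, and the kinase LATS1 at -0.52 and -0.40, with another probe at -0.37 and 0.42. VGLL1, a TEAD cofactor, was the 1 member of 25 past 2-fold in both by measured values, but it was well above background in sh1 alone, with a bound of at least 1.28-fold.

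Mesenchymal genes had the lowest list medians, at -0.59 in sh1 and -0.37 in sh2, percentiles 0 and 2.83. Of 19 measured members, VIM, LOX and CDH11, 3 in all, were at least 2-fold lower with both hairpins by measured values, and 2, VIM and LOX, with dim genes at their bounds. LOX, a collagen crosslinking enzyme, was at least 2.81-fold and 2.12-fold lower, and the cadherin CDH11 at least 1.82-fold and 1.37-fold lower. SNAI2, a repressor of epithelial genes, was at least 1.5-fold and 1.14-fold lower. S100A4, also a member of this list, went the other way, at 0.75 and 0.86. By measured values 4 members were at least 2-fold lower and 0 higher in sh1, and 6 were lower and 1 higher in sh2. The median over both hairpins was -0.48, but it was -0.15 when all 3 arrays had to be well above background and 0.01 with no filter on dim probes. Epithelial genes did not move the opposite way, with medians of 0.06 and 0.07 at percentiles 45.8 and 59.4. Of 30 measured members 1 passed 2-fold in both, KRT20, a keratin of differentiated intestinal epithelium, at -1.46 and -1.74. CDH1, encoding E-cadherin, stood at 0.16 and 0.32, CLDN7 at 0.38 and 0.38, and JUP at 0.19 and 0.30. KRT8 stood at 0.42 and 0.07, with another probe at -0.37 and -0.54.

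The direct comparison of the hairpins, free of the control array, found differences in genes of the intestinal epithelium and in VIM and MSN. CEACAM6, an adhesion molecule of intestinal epithelium, stood at -0.27 in sh1 and 2.78 in sh2, PHGR1 at -1.72 and 1.88, and FAM3D at -1.76 and 1.20. VIM and MSN were lower in sh1 than in sh2 by -4.23 and -3.25. In the other direction TGM6 stood at 3.99 and -0.18 (its other probe at -0.36 and -1.26), ANKFY1 at 2.98 and -1.12, TUSC1 at 1.86 and -1.40, AOAH at 3.70 and 0.97, and TRIM23 at 1.52 and -1.12. In all 1049 genes differed at least 2-fold between the hairpins, 624 higher and 425 lower in sh1. Of these, 250 and 163 were well above background on all 3 arrays. With median centring the split was 473 higher and 587 lower in sh1, so its direction depended on the scaling.

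Several lists stood apart in 1 hairpin line. Intestinal differentiation genes had a median of -0.04 in sh1 (percentile 21.6) and 0.41 in sh2 (percentile 100), and 12 of 31 measured members were at least 2-fold higher in sh2 against 1 in sh1, while 3 were at least 2-fold lower in sh1 and 0 in sh2. FABP1, the fatty acid binding protein of enterocytes, was at least 2.37-fold higher in sh2. The trefoil factor TFF2 stood at 0.82 and 1.78, and the nuclear receptor HNF4A at 2.72 and 0.27. The HNF4A signals in the control and sh2, 21.2 and 23.8, came from 1 spot each. They lay near the lowest signals well above background on those arrays, 15.1 and 18.3. Inflammatory and NF-kB genes had medians of 0.01 (percentile 21.7) and 0.57 (percentile 100), with 7 of 23 members at least 2-fold higher in sh2 and 1, the cytokine gene CSF2 at 1.08 and 1.36, higher in both. The chemokine CCL20 stood at -0.05 and 1.99, PTGS2 at 0.59 and 1.14, and IL1B at -1.29 and -0.55. Unfolded protein and amino acid stress genes had medians of 0.06 (percentile 42.5) and 0.44 (percentile 100), with 3 of 23 members at least 2-fold higher in sh2: ATF3 at 0.89 and 1.43 (other probes at 0.73 and 1.07, 0.77 and 1.26, and 0.23 and -0.03), DDIT4 at 0.87 and 1.38, and CHAC1 at 0.63 and 1.16. PPP1R15A stood at 0.62 and 0.71. The sh1 minus sh2 medians of these lists were -0.72, -0.55 and -0.33, each at percentile 0. Those of interferon response (-0.34) and cholesterol synthesis (-0.37) genes, described next, were at percentile 0 as well.

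Interferon response genes had medians of -0.21 (percentile 0.01) and 0.14 (percentile 98.1). Of 28 measured members, 3 were at least 2-fold lower in sh1 and 3 higher in sh2 by measured values, and 1 and 2 with dim genes at their bounds. IFI44 was at least 4.44-fold lower in sh1 and stood at -0.43 in sh2, and IFIT1 stood at -0.21 and 1.01. IFI44L was at least 1.62-fold lower in sh1 and 1.23-fold in sh2, and DDX60 stood at -0.64 and -0.10. Cholesterol synthesis genes had medians of -0.18 (percentile 0) and 0.12 (percentile 83.7), with none of 21 members past 2-fold; ACAT2 stood at -0.46 and -0.23, SQLE at -0.50 and 0.05, and MSMO1 at 0.03 and 0.40.

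Integrins, matrix genes and proteases had medians of 0.34 and 0.20 at percentiles 100 and 99.9, with 28 of 30 measured members under 2-fold with each hairpin. ITGA1 alone of them was at least 2-fold higher in both. S100A4 stood at 0.75 and 0.86, PLAUR, the urokinase receptor, at 0.82 and 0.54, and the laminin chain LAMA3 at 0.32 and 0.89. AP-1 and immediate early genes had medians of 0.12 and 0.19 (percentiles 96.1 and 99.8), with DUSP5 at 0.83 and 0.93, HBEGF at 0.56 and 0.72, and AREG at 0.78 and 0.49. TGF-beta response genes had medians of 0.10 and 0.08 (percentiles 87.9 and 77.8); CDKN2B was at least 1.88-fold higher in sh2, SMAD6 stood at -1.22 and -0.60 and BMP2 at 0.54 and 1.09.

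Cell cycle genes had medians of 0.11 and 0.01 (percentiles 83.9 and 3.66), with none of 32 past 2-fold; MKI67, a proliferation marker, stood at -0.45 and -0.36 (other probes at -0.65 and 0.09, and at -0.16 and -0.22), E2F2 at -0.62 and -0.41, CCNB1 at 0.32 and 0.38, and AURKA at 0.38 and 0.28. Targets of p53 had medians of 0.11 and 0.19 (percentiles 93.6 and 99.5), with MDM2 at 0.54 and 0.58 (other probes at 0.12 and 0.11, 0.36 and 0.11, and -0.05 and 0.38), BAX at -0.59 and -0.48 (another probe at -0.10 and -0.19) and SESN2 at 0.27 and 0.63. Wnt target and stem cell genes had medians of 0.03 and 0.05 (percentiles 37.2 and 49.4). Their member DKK1, a secreted Wnt inhibitor, was at least 8.73-fold lower in sh1 and 2.90-fold lower in sh2, DKK4 was at least 2.20-fold higher in sh2, and CD44 stood at -0.46 and -0.50, with another probe at 0.46 and 0.33. Hypoxia and glycolysis genes had medians of 0.18 and 0.04 (percentiles 99.6 and 62.0), and 2 of 23 were at least 2-fold lower in both: LOX and the mitophagy receptor BNIP3, at least 35.3-fold lower in sh1 and 5.79-fold lower in sh2. SLC2A3, a glucose transporter, stood at 1.85 and 0.68, and VEGFA at 0.39 and 1.0, with another probe at 0.58 and 0.59. Non-epithelial cell markers had medians of 0.06 and -0.11 (percentiles 77.8 and 47.1), with 10 of 17 measured and none past 2-fold in both. Housekeeping genes had medians of 0.04 and 0.01 (percentiles 18.8 and 10.4), and none of 20 passed 2-fold; TFRC stood at 0.11 and 0.38. For cell cycle and housekeeping genes the median over both hairpins was -0.01 with quantile normalization.

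**Figure D3:**
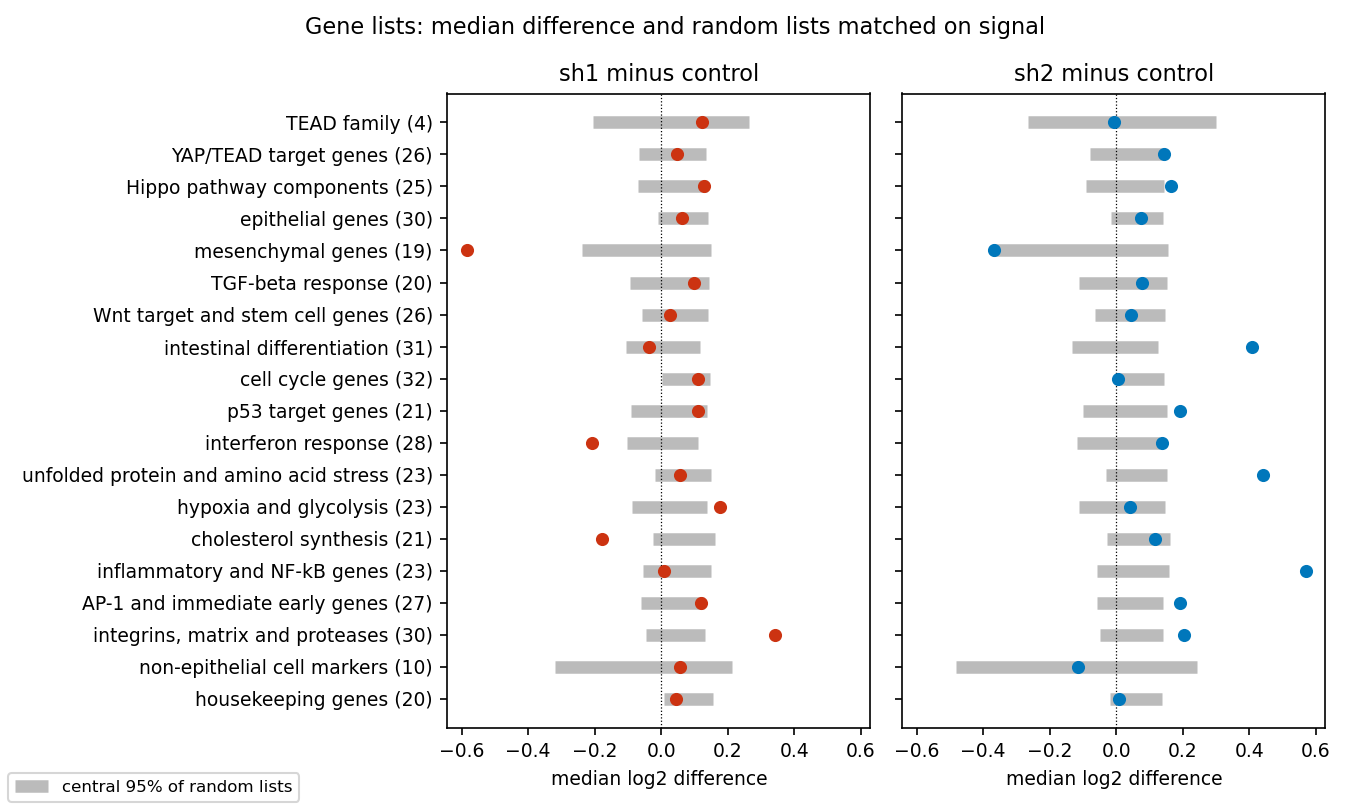
Median log2 difference from the control (x axis) of each of 19 gene lists (y axis, measured members in brackets) for sh1 (red, left) and sh2 (blue, right), with grey bars for the central 95% of 10000 random lists matched on signal. Mesenchymal genes lie lowest in both panels, at -0.59 and -0.37, while intestinal differentiation genes lie at -0.04 in sh1 and 0.41 in sh2.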

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

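All tests in this part were chosen after the results were seen. Opposite differences of at least 2-fold by measured values drew attention first: 12 genes were higher in sh1 and lower in sh2, and 15 were lower in sh1 and higher in sh2. The difference between hairpins was not tested for these genes. Of them, 4 and 2 were well above background on all 3 arrays: ANKFY1 (2.98 in sh1 and -1.12 in sh2), TUSC1 (1.86 and -1.40), TRIM23 (1.52 and -1.12) and CD28 (1.1 and -1.20), then PHGR1 (-1.72 and 1.88) and FAM3D (-1.76 and 1.20). Probes without a gene name lay outside the comparisons, and among 10653 measured ones 120 were at least 2-fold higher and 256 lower with both hairpins, 13 and 20 of them well above background on all 3 arrays. Transcript ENST00000389126 stood at 5.21 and 3.84, and AB007954 at -4.44 and -4.34.

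Intestinal differentiation genes stood higher in sh2 than in sh1, with 13 members at least 2-fold apart this way and 1, HNF4A, the other way. Among the 13 were PHGR1, CEACAM6, LGALS4 (-0.45 and 2.19) and REG4 (-0.50 and 1.78). Of 10000 random lists matched on signal, 0% had a median as low as -0.72, while a trend between the scans with signal alone would move such lists alike. This is the percentile by which the list stood out, so it is not a separate test. Interferon response and cholesterol synthesis genes, among others, also stood at percentile 0. Other effects of the scan stay open, since sh2 and its scan cannot be told apart. Artifacts of single spots stay open for most members: other measured probes exist for 4 of the 13, and 3 of these 5 probes were also at least 2-fold higher in sh2 (CEACAM1, CEACAM7 and REG4), but not those of MUC2. Less TEAD4 transcript in sh2 stays open too, as TEAD4 in sh1 minus sh2 was 0.0936 ± 0.204, with 1 array per line and only the scanner's error known. Effects of the separate scan on these genes in particular, of a hairpin on other transcripts, or of drift between stable lines may lie behind the pattern and were not tested, and the CEACAM paralogs may share probe signal.

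Genes at least 8-fold higher in sh1 and under 2-fold different in sh2 numbered 29 by measured values and 16 with dim genes at their bounds, against 14 in the mirror case for sh2 by measured values. Examples are MIXL1 (at least 23.4-fold) and GALR1 (at least 20.1-fold), and 24 of the 29 were not well above background in the control. The 16 leave out TMEM30CP, 243-fold higher in sh1 by measured values, whose probe was dim in the control but was given no bound. Each of the 29 was read by 1 spot. Of 3 with another measured probe, 0% had one at least 2-fold higher in sh1, but 3 genes are too few to decide on artifacts of single spots. Genes read by 10 spots, 4.08% of all measured genes, were absent from the set, with an exact one-sided binomial probability of 0.299 for so few. This is the lowest value 29 genes could give. The test therefore could not decide whether the transcripts truly differ.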

How the results depend on the processing

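The floor on dim values was chosen after the data were seen, and the other alternatives before. TEAD4 kept its direction and 2-fold size under all 8 alternatives run for it, from -1.32 to -1.22 in sh1 and from -1.41 to -1.19 in sh2. Counts below are higher and lower in sh1, higher and lower in sh2, higher and lower in both, and different between hairpins, set against 231, 443, 359, 679, 77, 229 and 1049. Normexp gave 64, 86, 94, 70, 14, 46 and 165, no filter on dim probes gave 492, 911, 797, 1068, 184, 419 and 1815, and a filter on all 3 arrays gave 82, 119, 199, 194, 26, 49 and 413, with the correlation between hairpins at 0.418 against 0.461. The 1.5-fold threshold gave 633, 1005, 899, 1519, 274, 491 and 2454 by its construction. Genes both at least 2-fold different and beyond the scanner-error limit numbered 430 lower in sh2, and 44 higher and 141 lower in both. Floored dim values gave 153 and 239 in sh1, 305 lower in sh2, 32 and 117 in both, and 606 between hairpins. The stricter filter and the floor act on dim genes alone, so signal over background limits these counts. Normexp added an offset of 50 to every spot, which shrinks log2 differences of dim genes by construction. How much of the normexp change came from the offset was not tested.

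With the hairpins as 2 replicates, limma at an adjusted p under 0.05 called 2 genes higher and 1 lower (709 in all at an unadjusted p under 0.05), with 1 residual degree of freedom and the lone control assumed to vary like the hairpins. TEAD4 had an adjusted p of 0.136 in this limma fit. Quantile normalization gave 100 higher and 187 lower in both, sharing 76 and 185 genes with the main counts, and the authors' table gave 101 and 188, sharing the same numbers. Normexp shared 14 of its 14 and 45 of its 46, and the floor all of its 32 and 117. Of list medians over both hairpins, 105 values lay within 1 SD of matched random lists' medians (0.031 to 0.13, by list) of the main one and 47 moved by more. Median centring moved 18 of 19 lists and turned the sign of 3, but it shifts every gene of an array alike. All list medians rose by the same amount under it, so the lists kept their places relative to each other. Quantile normalization moved 10 lists and turned 4. Cholesterol synthesis went from -0.03 to 0.09 with median centring and to -0.09 with quantile normalization. Interferon response went from -0.02 to 0.10 with median centring. No paired analysis was possible because each group has 1 array.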

Other observations

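All tests in this part were chosen after the results were seen. Cancer-testis genes, which are silent in most adult tissues and can be active in tumours, were picked by name after MAGEA2B appeared among the lowest genes, and the choice of names was narrowed once to drop look-alike symbols outside the family. Of 25 measured members, 8 were at least 2-fold lower with both hairpins by measured values, 6 were with dim genes at their bounds, and 0 were higher with both. SPANXA1 was at least 35.7-fold lower in sh1 and stood at -1.85 in sh2, MAGEA12 was at least 20.5-fold lower in sh1 and stood at -2.11 in sh2, CT83 was at least 2.31-fold and 1.75-fold lower, and CSAG1 stood at -2.08 and -1.47. Among other members, CSAG3 stood at 0.04 and -0.25 and PAGE2 at 0.41 and 1.06. Their median was -0.19 in sh1 (percentile 8.25 of matched random lists) and -0.73 in sh2 (percentile 0.02), in a list chosen on these arrays, and members of the MAGEA and SPANX families are paralogs whose probes cannot be taken as separate.

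Genes at least 16-fold lower in sh1 and at least 2-fold lower in sh2 numbered 34 by measured values and 13 with dim genes at their bounds, including VIM, MSN, BNIP3, the protease inhibitor TFPI2 (at least 31.3-fold in sh1, -1.64 in sh2) and CMTM3 (at least 21.9-fold, -1.65). Artifacts of single spots are argued against for the 5 genes with another measured probe, of which 100% had one at least 2-fold lower in sh1, and for GNG11, read by 10 spots, and stay open for the other 28, while less TEAD4 left in sh1 stays open as well: TEAD4 in sh1 minus sh2 was 0.0936, the opposite sign to this explanation, but with the scanner's error alone. A candidate explanation is loss of 1 kind of cell from a mixed culture, which would lower its genes to 1 share, about 27.8% in sh2 by the median of -1.85 over 9 genes bright enough to read a 16-fold loss. The test was revised after its result was seen and its versions did not give the same answer: the plain SD over these 9 genes was 1.62, above the 0.137 to 0.760 of genes drawn at like signal, a robust SD was 0.300 (0.0784 to 0.499), and the first version, a plain SD over 22 genes, was 0.411 (0.258 to 0.732). The gap rests on ITGA4, not well above background in sh2: at its bound of -4.48 the plain SD was 0.900, and without it 0.314, with the other 8 genes between -2.53 and -1.64, so the explanation stays open, and choosing genes lower in sh2 could narrow the spread of the 22, though it removed 0 of the 9. These versions covered sh2 alone. Of the 9, those well above background in sh1 stood there at -6.38 ± 0.21 (VIM), -4.99 ± 0.30 (MSN), -4.88 ± 0.27 (MAGEA2B) and -4.06 ± 0.22 (CAVIN3). They lie further apart than their scanner errors, while 1 share would place them together. That spread was not tested, and each value came from 1 spot on 1 array.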
